A study of Mus musculus with 4 samples.

How the data were processed

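The data were 4 mouse liver sections measured with Visium, a spatial assay in which a tissue section is laid on a slide printed with a hexagonal array of barcoded spots, and the messenger RNA of the tissue over each spot is captured, given the spot's barcode and a unique molecular identifier (UMI), and sequenced. Per the labels, the tissue was fresh frozen, embedded and sectioned, and the sections were stained and imaged before RNA capture. The sections came from 2 mouse models of liver cancer, with 2 sections per model and 1 section at each labelled time. The group names STAM16w, STAM20w, DEN22w and DEN30w are those of the labels, with w read as weeks. The labels do not say whether weeks count the age of the animal or the time since treatment.

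The deposited matrices hold UMI counts per gene and spot, whole numbers that the authors did not normalize. Space Ranger 1.3.1, STAR and the mouse genome build mm10 are named, per the submitters' processing notes; the settings and the gene annotation version were not given in the sources used here. Per the file headers, each matrix lists 32285 genes, of which 78 symbols occur more than 1 time; these were kept apart by their Ensembl identifiers. Spot positions and the mark of spots over tissue came from the deposited position tables, and the deposited matrices hold spots over tissue. Reads shared by near-identical genes can be lost or divided unevenly in such counts, so values of the Mup, Cyp4a, Cyp2a, Saa, immunoglobulin and haemoglobin genes are uncertain as values of single genes. Tissue images, cell segmentation and any annotation of tumour tissue were not used here. Gene positions were taken from the RefSeq table of assembly GRCm38.p6, the assembly of mm10, which held 26259 of the 32285 symbols.

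Spots with at least 500 UMIs and at least 250 detected genes were kept: 2080 of 2082 in STAM16w, 2833 of 2895 in STAM20w, 2746 of 2804 in DEN22w and 2968 of 3073 in DEN30w. Kept spots held 20700642, 40008457, 22471682 and 34880049 UMIs, with medians of 9711.5, 12761, 7302.5 and 9423 UMIs per spot. A spot can hold parts of several cells of different types, so spots were not called as cell types and no doublet caller was run. CPM are UMIs of a gene per 1e+06 UMIs of the section, region or spot class. Exact Poisson intervals of CPM and exact binomial (Clopper-Pearson) intervals of shares, both at 95%, cover counting error only, as do the exact binomial intervals of a ratio of UMIs between spot classes. A level of 0 was replaced by 3 counts, over the group's summed UMIs, for a lower bound of a fold.

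The choices below were fixed before the data were examined unless said otherwise. Mycn-detected spots were those with at least 1 Mycn UMI. Each was matched, without replacement, to the spot of the same section with 0 Mycn UMIs, no contact with a Mycn-detected spot and the nearest UMI total within 0.1 on the log10 scale. Neighbour spots had 0 Mycn UMIs and touched a Mycn-detected spot; they were matched in the same way to distant spots, which touched none and had not served in the first comparison. Counts were summed per section and spot class, since the section and not the spot is the replicate, and the sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, TMM factors, filterByExpr, section as a block, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The plan required 20 pairs in each of at least 3 sections. The Mycn-detected spots fell short of it, so the planned test of these spots and of its interaction with the model were not made; a fit of the same sums without the minimum, and the interaction of the neighbour comparison with the model, were added after seeing the data. The models were compared on whole-section sums, 2 sections against 2, with edgeR's quasi-likelihood test and no covariate.

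Later and earlier sections of a model were compared without a test, as 1 section stood on each side: genes at 50 CPM or more in the higher section were counted where they differed by at least 2-fold. Gene lists, 37 in all with 458 genes of which 457 were found among the genes of the files, were tested in the fitted comparisons with fry and camera of limma 3.58.1 on voom values. Camera was run with a preset correlation of 0.01 and with an estimated one. Between times, a list's median log2 ratio over members at 1 CPM or more was placed among the medians of 10000 random lists of genes of similar mean expression. After seeing the data, the level of each gene named between times was also computed without the region where it was highest, and is given for genes whose printed fold or level changed by more than 1.5 times, Mycn apart, whose interval held 0. Detection of Mycn was compared after thinning each spot to 2000 UMIs. The grouping of Mycn-detected spots was measured by the number of touching pairs and by Moran's I, a measure of whether adjacent spots have alike values, each set against the 200 genes of the same section nearest in number of detected spots. Regions were found per section by Leiden clustering (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15; counts scaled to 10000 per spot, log1p, 2000 variable genes, 30 principal components, 15 neighbours, resolution 0.6) and named by their leading genes.

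Genes were named by a fixed rule, and predicted genes were counted but not named. In the Mycn comparisons these were the 15 highest and 15 lowest log2 fold changes past the threshold with the same sign in every section and, as fewer than 10 passed, the 10 with the smallest p as well. Between models they were the 15 highest and 15 lowest past the threshold with a mean CPM of at least 10 and no overlap between the models' sections, and in the interaction the 5 highest and 5 lowest past it. Between times they were the 10 highest and 10 lowest ratios of each model and the 10 highest and 10 lowest by the smaller of both models' ratios among genes moved at least 2-fold in both. Of each list described, up to 4 members were named, those with the smallest adjusted p or, between times, the highest mean CPM. A region was described by the 5 genes at 50 CPM or more with the highest fold over the rest of its section. Mycn and Myc were always named. A gene outside this rule is said to have been chosen after its value was seen.

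Alternatives were DESeq2 1.42.0 in place of edgeR, no filter on low counts, no section block, no depth matching, matching within the same region, distant spots at least 3 steps away, all deposited spots, sums without mitochondrial and haemoglobin genes, thinned sums, other thinning depths, a floor of 20 CPM, other clustering settings and leaving out each section in turn. Spots of at least 5000 UMIs and sums without the regions led by haemoglobin or mitochondrial genes were added after seeing the data. The tests were tested on negative binomial counts simulated from fits of the real sums, with 200 changed genes. Counts were drawn independently per gene and sum. Genes that move together in a patch of tissue were thus not simulated, and real data may hold more false calls. The neighbour test found 82.0% of genes changed 2-fold and 98.5% of genes changed 4-fold, with 7 and 9 false calls among 6644 genes. The fit of Mycn-detected spots found 76.5% and 91.5%, with 3 and 7 false calls among 1803 genes. The model test found 0% at 2-fold, 0% at 4-fold and 82.5% at 8-fold, with 0, 1 and 18 false calls among 14417 genes.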

Results

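Spatial transcriptomes were collected from 4 liver sections of 2 mouse models of hepatocellular carcinoma to ask where Mycn is expressed in the diseased liver and what surrounds it. STAM is a metabolic model in which liver cancer develops on fatty, inflamed liver with diabetes, and was sampled at 16 and 20 weeks. DEN+CCl4 combines diethylnitrosamine, a carcinogen that damages DNA, with carbon tetrachloride, a toxin that scars the liver, and was sampled at 22 and 30 weeks. Each model and time had 1 section, and nothing in the labels says that the sections came from separate animals, so p-values between sections measure only the spread between these 4, age and animal together. STAM16w had 2080 spots with a median of 9711.5 UMIs and 2822 genes, STAM20w 2833 spots with 12761 UMIs and 3496 genes, DEN22w 2746 spots with 7302.5 UMIs and 2552.5 genes, and DEN30w 2968 spots with 9423 UMIs and 3168 genes. Mitochondrially encoded genes took 2.10%, 3.67%, 1.31% and 1.55% of the UMIs in this order of sections, ribosomal protein genes 4.56%, 7.81%, 3.48% and 3.64%, and Alb, the gene of serum albumin, 1.19%, 2.33%, 3.56% and 2.55%. Ddx3y, on the Y chromosome, had 592, 1034, 681 and 1168 UMIs, while Xist, the transcript of the inactive X chromosome, had 0, 0, 1 and 1 UMIs.

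Mycn (ENSMUSG00000037169; chromosome 12, 12936093 to 12941836 in GRCm38.p6), a transcription factor of the MYC family, was seen in under 1 in 200 spots of every section. The counts were 10 spots in STAM16w (0.481%, exact binomial 95% interval 0.231 to 0.882%), 10 in STAM20w (0.353%, 0.169 to 0.648%), 11 in DEN22w (0.401%, 0.2001 to 0.716%) and 14 in DEN30w (0.472%, 0.258 to 0.790%), and every one of these spots held 1 Mycn UMI. As a level this was 0.483 CPM in STAM16w (exact Poisson 95% interval 0.232 to 0.888), 0.250 in STAM20w (0.120 to 0.460), 0.490 in DEN22w (0.244 to 0.876) and 0.401 in DEN30w (0.219 to 0.673), and the 4 intervals overlapped. Thinned to 2000 UMIs per spot, 3 of 2038 spots in STAM16w, 2 of 2623 in STAM20w and 3 of 2630 in DEN30w kept a Mycn UMI (0.147%, 0.0762% and 0.114%). In DEN22w 0 of 2547 did, which allows a share of up to 0.145% by the exact interval. A difference in Mycn between the sections was not detectable at this depth.

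Myc (ENSMUSG00000022346; chromosome 15, 61985341 to 61990361), the paralog of Mycn, was higher than Mycn in every section, beyond counting error. Its level was 6.52 CPM in STAM16w (5.47 to 7.72), 17.8 in STAM20w (16.5 to 19.2), 1.78 in DEN22w (1.27 to 2.42) and 5.33 in DEN30w (4.59 to 6.16). Spots with a Myc UMI made up 6.15%, 19.1%, 1.46% and 5.96% of the sections before thinning and 1.86%, 2.59%, 0.314% and 1.03% after it. Mycl, another MYC family gene, stood at 9.85, 7.95, 7.08 and 5.76 CPM.

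**Figure D1:**
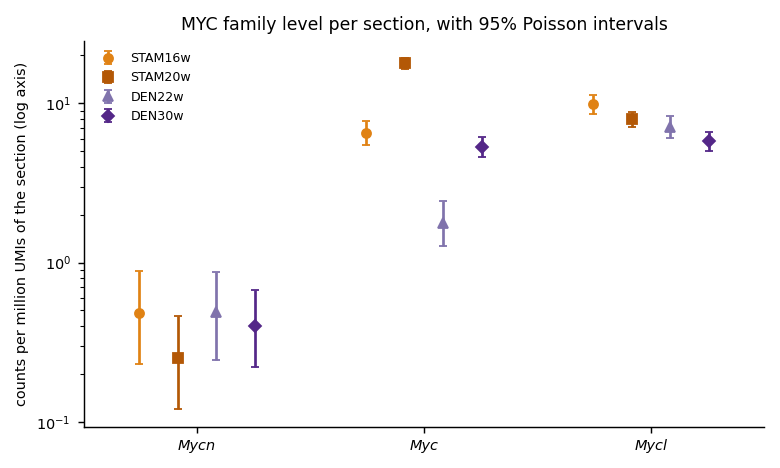
Level of Mycn, Myc and Mycl in each section in CPM on a log axis, with exact Poisson 95% intervals as bars (1 section per point). Mycn lies between 0.250 and 0.490 CPM with overlapping intervals, and Myc spans 1.78 to 17.8 CPM.

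Whether Mycn-detected spots lay together was asked within each section. No 2 Mycn-detected spots touched in any of the 4 sections. Among the 200 genes of each section seen in about as many spots, 78.5% (STAM16w), 82.5% (STAM20w), 84% (DEN22w) and 79% (DEN30w) also had 0 touching pairs. Moran's I of Mycn stood at percentiles 27, 53, 12.5 and 53 of these genes. Counting spots up to 2 steps apart, 1 pair was found, in DEN22w, 2.55 times the share of Mycn-detected spots in that section and at percentile 70.5 of the same genes.

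Clustering each section alone gave 6 regions in STAM16w, 10 in STAM20w, 4 in DEN22w and 5 in DEN30w. STAM20w held compact patches. A patch led by Cpe, Slc7a11, Gpx2, Nkd1 and Maoa covered 277 spots (9.78%), and 85.6% of the spots adjacent to its members belonged to it. A patch led by Cib3, Akr1c18, Gsta1, Serpina12 and Serpinb6b covered 272 spots (9.60%) with 90.2% such contacts, and a patch led by H19, Afp, Cyp3a44, Fabp4 and Fabp5 covered 222 spots (7.84%) with 94.6%. STAM16w held a patch of 19 spots led by Mtmr11, Fndc10, Nkd1, Nupr1 and Fmr1nb (0.913% of spots, 70.2% of contacts). In DEN22w, spots led by Gpnmb, Gstm3, Meg3, Mmp12 and Cd68 made up 12.1% of the section with 30.7% of contacts within the region, and in DEN30w spots led by Meg3, Sprr1a, Cd74, Cyp2a5 and Tmsb10 made up 28.6% with 56.4%.

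In STAM16w, 6 of the 10 lay in the region led by Lhpp, Meg3, Slc13a3, Slc1a2 and Cyp2c29, which held 26.1% of the spots; their share there was 1.11% (0.407 to 2.39%). In STAM20w, 3 of the 10 lay in a region of 71 spots led by Ankrd1, Dcdc2a, Fgfbp1, Lce6a and Myo5c (4.23%, 0.880 to 11.9%, against 0.353% in the section), which had a median of 3088 UMIs and 10.5% mitochondrial UMIs, and 1 lay in the patch led by Cpe. The regions led by mt-Atp8 and by Ighg2b, with 17.2% and 20.1% of the spots of STAM20w, held 0 (upper limits 0.756% and 0.646%). Apart from the region led by Ankrd1, the interval of every region of the 4 sections held its section's share. Shares of spots grow with depth, and by level Mycn was highest in the region led by Ankrd1 (11.3 CPM against 0.250 in STAM20w). Next was the region of DEN30w led by Ikbkb and Metap1d (2.04 CPM against 0.401 in DEN30w). That region had a median of 1920 UMIs per spot against 9423 in DEN30w. Each level came from 3 UMIs, and no interval of these levels was computed. Myc stood at 37.4 CPM in the patch led by Cpe (251 UMIs, exact Poisson 95% interval 33.0 to 42.4) against 13.9 in the other spots of STAM20w, and at 27.5 CPM in the region led by S100g, Col1a1 and Col1a2 (75 UMIs, 21.7 to 34.5) against 17.1. In the patch led by Mtmr11 it stood at 27.0 CPM, from 5 UMIs (8.78 to 63.1), against 6.34 in the other spots of STAM16w. In DEN22w Myc was 3.54 CPM in the region led by Gpnmb, from 9 UMIs (1.62 to 6.71), against 1.56 elsewhere, and 3.59 CPM in the region led by Hba-a2 and Hba-a1, from 4 UMIs (0.979 to 9.20). In DEN30w it was 7.72 CPM in the region led by Meg3 and Sprr1a (67 UMIs, 5.99 to 9.81) against 4.54 elsewhere.

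**Figure D2:**
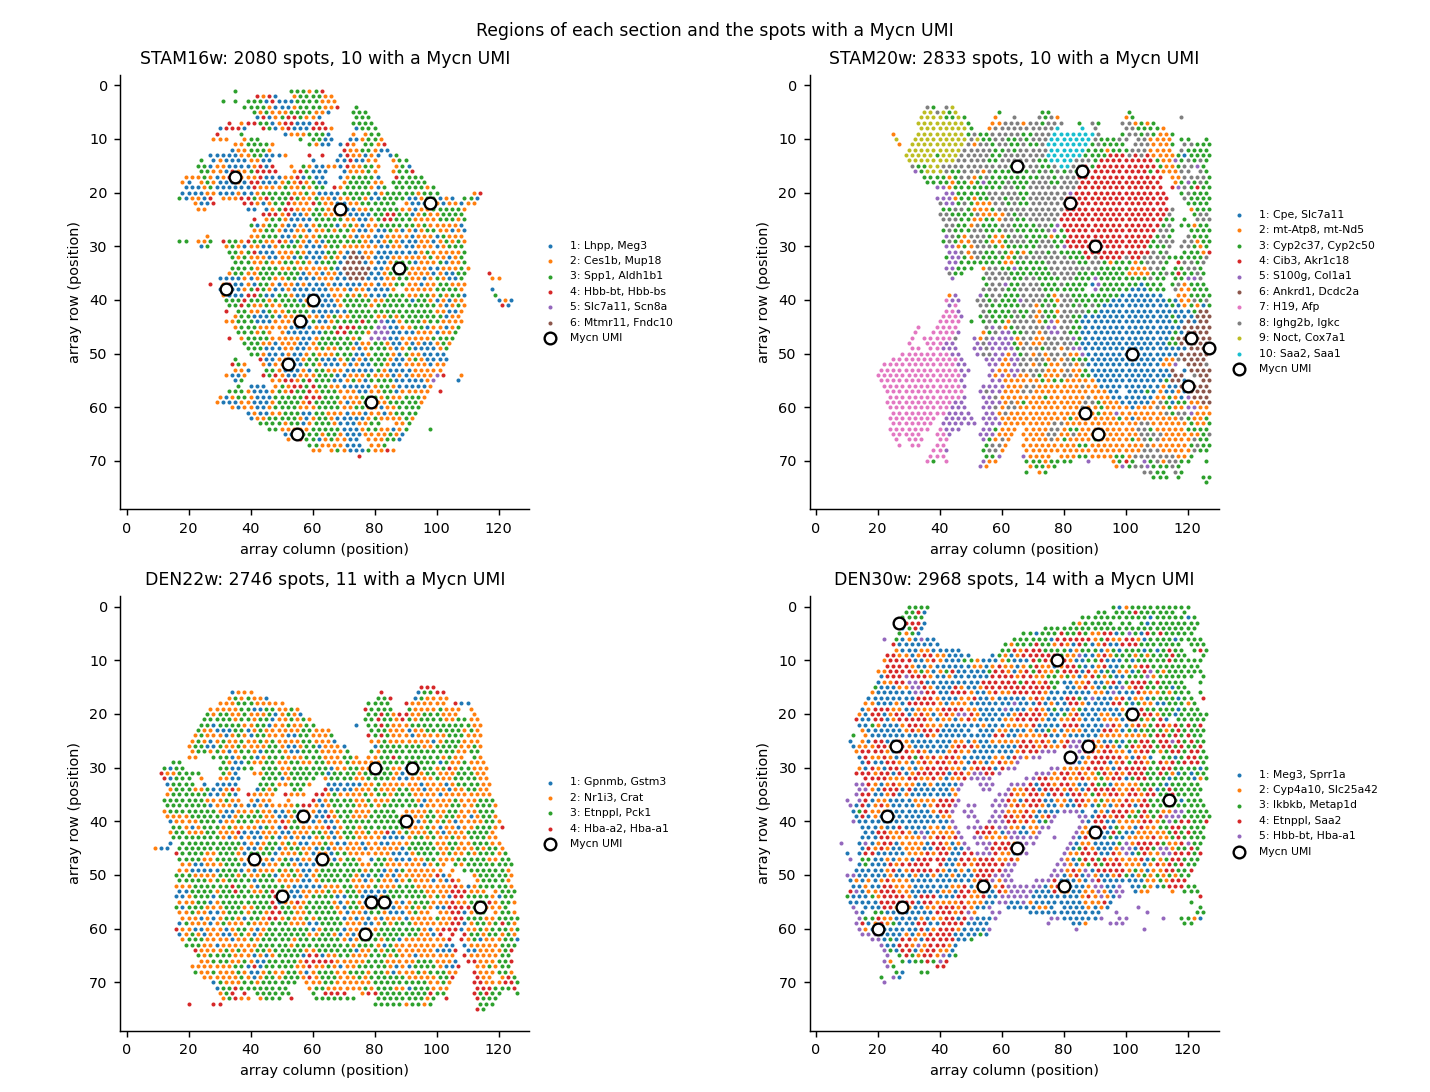
Maps of the 4 sections by array column and array row (positions on the slide), with each kept spot coloured by its region, named by leading genes, and spots with a Mycn UMI as open circles. The 10, 10, 11 and 14 Mycn-detected spots lie apart from each other, and STAM20w shows compact patches such as those led by Cpe, Cib3 and H19.

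What distinguishes a Mycn-detected spot from a spot of the same depth was asked next. Spp1, the osteopontin gene, had a log2 fold change of 1.07 (SE 0.34) with per-section values of 0.46, 2.88, -0.74 and 0.00 in STAM16w, STAM20w, DEN22w and DEN30w. Fasn, the fatty acid synthase gene, had 0.56 (SE 0.17) and was higher in 4 of 4 sections, as were Lrpprc at 0.90 (SE 0.30) and Ifi27 at 0.51 (SE 0.17), while Retsat was lower in 4 of 4 at -0.51 (SE 0.18). Nfe2l1 (-1.07), Oat (0.52), Cyp2a5 (0.54), Igfbp1 (0.64) and Krt18 (0.49) completed the 10 genes with the smallest p. None of the 1803 genes passed in edgeR's quasi-likelihood test (74 at an unadjusted p under 0.05; these 10 all had adjusted p = 0.9998), and DESeq2 gave 0 as well (0 at an unadjusted p under 0.05). The fit rested on 10, 10, 11 and 14 pairs of spots, short of the 20 planned, and was chosen after seeing the data. Of 20 gene lists, fry called 0 (1 at an unadjusted p under 0.05; lowest adjusted p = 0.797); camera with preset correlation called 5, and 0 held (lowest adjusted p = 0.595 with an estimated correlation).

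The spots that touched a Mycn-detected spot were compared with distant spots of the same section and depth, to ask what surrounds Mycn. As every detected spot held 1 Mycn UMI, spots with 0 are undetected and may still hold Mycn RNA. Next to Mycn-detected spots, Meg3 (ENSMUSG00000021268; chromosome 12, 109540996 to 109571729), an imprinted long noncoding RNA, rose by 0.71 on the log2 scale (SE 0.16, edgeR adjusted p = 0.0105), with 0.61, 0.66, 0.97 and 0.70 in STAM16w, STAM20w, DEN22w and DEN30w. Gstm3, a glutathione transferase, rose by 0.31 (SE 0.07, adjusted p = 0.0105 in edgeR), with 0.59, 0.67, 0.67 and 0.042 in the same order. Arg1 (ENSMUSG00000019987; chromosome 10, 24915207 to 24927470), the urea cycle enzyme arginase, fell by 0.23 (SE 0.06, edgeR adjusted p = 0.0389), with -0.31, -0.29, -0.24 and -0.038. These 3 had the same sign in 4 of 4 sections, although Gstm3 and Arg1 were near 0 in DEN30w. In all, 6 genes rose and 6 fell among 6644 tested (418 at an unadjusted p under 0.05).

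The other 9 called genes had the sign of their estimate in 3 of 4 sections. Nupr1 (ENSMUSG00000030717; chromosome 7, 126623246 to 126625470), a stress-response gene, rose by 1.66 (SE 0.13, edgeR adjusted p = 2.7e-31), with 1.76 in STAM16w, 1.99 in STAM20w, 1.32 in DEN22w and -0.16 in DEN30w. The DEN22w value rested on 5 UMIs in neighbour spots and 2 in distant spots (exact binomial 95% interval of the log2 ratio -1.29 to 4.71). Cyp1a2 (ENSMUSG00000032310; chromosome 9, 57676937 to 57683655), a cytochrome P450 of hepatocytes around the central vein, rose by 0.37 (SE 0.07, edgeR adjusted p = 5.2e-05), with 0.65, 0.94, -0.04 and 0.24. Cyp2a5 rose by 0.29 (SE 0.06) and Ighm, an immunoglobulin heavy chain gene, by 1.27 (SE 0.22; -2.58, 0.82, 0.42 and 1.75 in the 4 sections, the first from 1 UMI against 6, interval -8.11 to 0.46). Cyp2f2, a cytochrome P450 of hepatocytes around the portal vein, fell by 0.28 (SE 0.06), and the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 fell by 0.93, 0.92 and 0.98, except in DEN22w, where all 3 were higher, from 8 to 20 UMIs in neighbour spots. Saa1, an acute phase gene chosen after its value was seen, fell by 0.24 (SE 0.06). Sections differed beyond counting error for Nupr1 (interval 1.70 to 2.29 in STAM20w, upper limit 0.67 in DEN30w). They also did for Hbb-bs (-1.86 to -1.03 in STAM20w, lower limit -0.31 in DEN22w) and Ighm (upper limit 0.46 in STAM16w, lower limit 1.22 in DEN30w). The SEs of these genes (0.13, 0.14 and 0.22) are small against this spread. Section intervals also lay apart for Cyp1a2 (0.70 to 1.19 in STAM20w, upper limit 0.19 in DEN22w). For Gstm3 they did so as well (0.40 to 0.94 in STAM20w, upper limit 0.17 in DEN30w), and for Cyp2f2, Hba-a1, Hba-a2 and Saa1. The p-values of all these genes thus do not measure how well a change repeated across sections. Of the neighbour spots' Nupr1 UMIs, 90.1% in STAM16w and 52.4% in STAM20w lay around 1 Mycn-detected spot, as did 74.8% of the Cyp1a2 UMIs in STAM20w but 17.9% in STAM16w. DESeq2 called 0 genes (32 at an unadjusted p under 0.05), the fit without section block 0 (29), and the fit without STAM20w 1, which was not among the 12. Matched within the same region, 3 genes were called, Nupr1 and Hbb-bs of the 12 among them, Meg3 had 0.25 (SE 0.15) and did not pass, and Ighm was not tested.

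**Figure D3:**
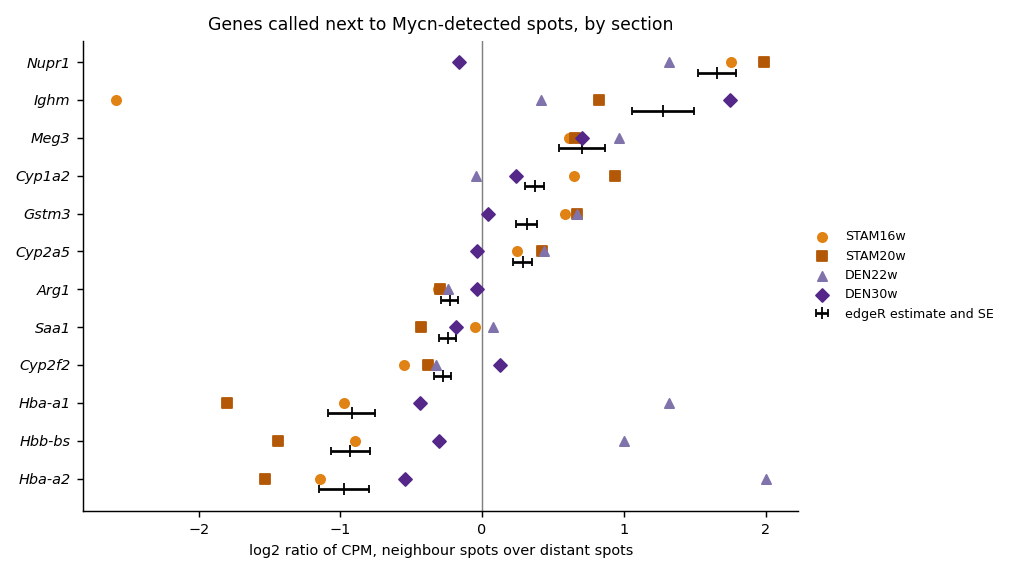
Log2 ratio of CPM in neighbour spots over distant spots for the 12 called genes, as 1 point per section, with the edgeR estimate and its standard error as a bar under each row of points. Meg3, Gstm3 and Arg1 have the same sign in 4 of 4 sections, and Nupr1 spans -0.16 to 1.99. For all but Meg3, Arg1 and Cyp2a5 sections differed beyond counting error, and the standard error does not measure the spread between sections.

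By list, all 11 measured genes of pericentral hepatocytes had positive fold changes next to Mycn-detected spots; Cyp1a2 and Cyp2a5 passed over all genes, and 2 passed when adjusted over the list alone. All 15 periportal genes had negative fold changes, with 1 passing over all genes (Cyp2f2) and 7 adjusted over the list alone. Of 11 acute phase genes 1 fell over all genes and 5 adjusted over the list alone, of 11 NRF2 and xenobiotic defence genes 1 rose (Gstm3) and 3 adjusted over the list alone, and of 4 erythroid genes 3 fell by either count. No MYC target or ribosome biogenesis gene passed among 18 (median log2 fold change 0.00), nor did any of 6 proliferation genes. Fry called 0 of 33 lists (4 at an unadjusted p under 0.05; lowest adjusted p = 0.278). Camera with preset correlation called 14, of which 0 held, with a lowest adjusted p = 0.2002 with an estimated correlation. Median, mean and test differed in sign for the proliferation, endothelial, Kupffer cell, stem cell marker, lipid droplet, cholesterol synthesis, glucose, antigen presentation and male-biased lists.

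The neighbour comparison was then set against the model, as a test added after seeing the data. The change next to Mycn-detected spots was larger in STAM than in DEN+CCl4 by 0.69 on the log2 scale for Cyp1a2 (SE 0.14, edgeR adjusted p = 0.00595) and by 1.92 for Nupr1 (SE 0.41, edgeR adjusted p = 0.0121), the only genes past the threshold. By section, Cyp1a2 had 0.65 and 0.94 in STAM and -0.04 and 0.24 in DEN+CCl4. Nupr1 had 1.76 and 1.99 in STAM, and 1.32 (5 UMIs against 2) and -0.16 in DEN+CCl4. With 2 sections per model, these p-values do not measure how well a difference between models repeated across sections. DESeq2 called 0 genes for this difference (7 at an unadjusted p under 0.05), and edgeR without the filter on low counts 0 (485).

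The models were compared on whole sections, 2 against 2. The models share no labelled time, so a difference between models cannot be told apart from a difference in time. The genes that rose most in STAM included the lipid droplet genes Fitm1 and Cidec and the Cyp4a genes Cyp4a14 and Cyp4a10. Cyp4a14 (ENSMUSG00000028715; chromosome 4, 115486200 to 115496158), a fatty acid hydroxylase induced through PPARα, rose by 7.39 on the log2 scale (SE 0.58, edgeR adjusted p = 0.0196), with 2004 ± 1141 CPM in STAM and 13.1 ± 0.977 in DEN+CCl4 (mean ± SD, n = 2 each). Fitm1 (ENSMUSG00000022215; chromosome 14, 55575674 to 55576952), a protein of lipid droplet formation, rose by 5.96 (SE 0.26, edgeR adjusted p = 0.00853) from 2.87 ± 0.162 to 159 ± 19.01 CPM. Glul (ENSMUSG00000026473; chromosome 1, 153899929 to 153909723), the glutamine synthetase of hepatocytes around the central vein, rose by 3.38 (SE 0.31, edgeR adjusted p = 0.0298), from 55.8 ± 2.88 to 512 ± 81.6 CPM. In all, 42 genes were higher and 21 lower in STAM among 14417 tested (3305 at an unadjusted p under 0.05), with both sections of one model above both of the other for all 63; such separation held for 56.5% of tested genes, against 33.3% by chance.

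Further genes higher in STAM were Cidec (6.68), a lipid droplet protein, Cyp4a10 (5.03), Vnn1 (4.69), Nlrp12 (4.58), Cyp2a4 (4.56), Cyp2c38 (4.42), Mogat1 (4.30), an enzyme of triglyceride synthesis, Rgs16 (3.89), Clstn3 (3.48), Cyp4a31 (3.34), Cyp2c37 (2.96) and mt-Nd4l (2.80), with adjusted p from 0.0142 to 0.0461 in edgeR. The Cyp4a and Cyp2 genes have close paralogs, so their single values are uncertain. Lower in STAM were Cyp26a1, which breaks down retinoic acid, by -7.04 (SE 0.49, edgeR adjusted p = 0.0193), C1rb (ENSMUSG00000098470; chromosome 6, 124570430 to 124581044), a complement protease, by -6.34 (SE 0.30, edgeR adjusted p = 0.00853), and Hamp2, a paralog of the iron hormone gene Hamp, by -5.89 (SE 0.42). Hamp2 fell from 758 ± 241 CPM in DEN+CCl4 to 11.5 ± 1.81 in STAM. Slc10a2 (-4.92), a bile acid carrier, Slc3a1 (-2.84), Csad (-2.09), an enzyme of taurine synthesis, and Mmp2 (-1.89), a matrix protease, were also lower. Sptlc3 had 0 UMIs in both DEN+CCl4 sections and was at least 122-fold higher in STAM, and Ifi44l and Ifi202b had 0 UMIs in both STAM sections and were at least 104-fold and at least 77.3-fold lower (floor of 3 counts over the summed sections; chosen after their values were seen). Mycn did not pass this test (log2 fold change -0.15, SE 0.61, edgeR adjusted p = 0.910), and Myc had 1.93 (SE 0.60, edgeR adjusted p = 0.149). DESeq2 called 1517 genes, which included the 63, and edgeR without the filter on low counts 1872; leaving out DEN22w or DEN30w left 5 and 2 calls, and leaving out STAM16w gave 922.

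**Figure D4:**
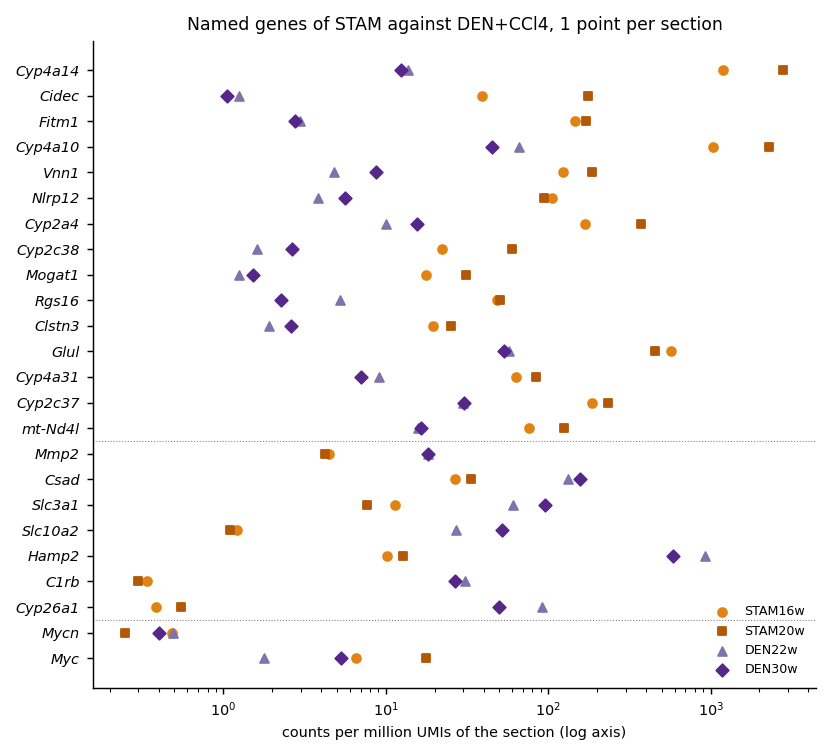
Level in CPM on a log axis of the 24 genes named in the comparison of models, with 1 point per section. The STAM sections lie above both DEN+CCl4 sections for genes such as Cyp4a14, Fitm1 and Glul and below them for Cyp26a1, C1rb and Hamp2, while the sections overlap for Mycn.

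By list, pericentral hepatocyte genes were the only one of 37 lists called by fry (adjusted p = 0.0246, limma; 8 lists at an unadjusted p under 0.05), and camera with an estimated correlation did not call it (adjusted p = 0.847). Of its 12 genes, Glul rose over all genes; adjusted over the list alone 6 rose, among them Slc1a2 (6.57) and Cyp2a5 (3.67), and Cyp2c29 fell (-1.32). Among lipid droplet and uptake genes, 4 of 11 rose over all genes, Fitm1, Mogat1, Cidea (7.27) and Cidec, and 9 adjusted over the list alone. Among fatty acid oxidation and PPARα targets, Vnn1, Cyp4a14 and Cyp4a10 rose of 15, and 9 adjusted over the list alone. Mitochondrially encoded genes rose for 2 of 13, mt-Nd4l and mt-Nd5 (2.62), and for 10 adjusted over the list alone. Of 12 Wnt and β-catenin targets 1 rose over all genes (Glul) and 5 adjusted over the list alone, of 15 NRF2 and xenobiotic defence genes 1 (Gsta1, 2.69) and 7, and of 6 female-biased liver genes 1 (Cyp2a4) and 5. No interferon response gene passed over all genes, while 10 of 13 rose adjusted over the list alone, such as Isg15 (1.83), Usp18 (1.72) and Oas1a (1.64).

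In the other direction, 0 of 17 cholesterol synthesis genes passed over all genes and 8 fell adjusted over the list alone, such as Nsdhl (-1.31) and Fdps (-1.44). Of 15 periportal genes 0 passed over all genes; adjusted over the list alone 6 fell, such as Aldh1b1 (-1.90) and Sds (-1.78), and Hsd17b13 rose (1.07). Of 12 unfolded protein and stress response genes 0 passed over all genes; adjusted over the list alone 4 fell, such as Sdf2l1 (-1.99) and Hyou1 (-2.12), and 2 rose, Fgf21 (3.17) and Trib3 (1.39). For the following no gene passed over all genes. Adjusted over the list alone, Mcm2 (1.60) and Pcna (0.73) rose and Mki67 (-1.29) fell among 20 proliferation genes, Folr2 (2.13) and Clec4f (1.12) rose among 12 Kupffer cell genes, Acly (-1.29) and Acaca (-1.14) fell among 14 lipid synthesis genes, and Nr0b2 (-1.83) and Abcb11 (-1.35) fell among 12 bile acid genes. A lone member passed in the oncofetal and liver tumour list (Peg3, 2.32), erythroid (Hbb-bs, 1.84), acute phase (Saa3, 1.71), hypoxia (Bnip3, 1.33), antigen presentation (Ciita, -2.14) and immediate early lists (Dusp1, -2.08). By either count 0 members passed among MYC family, MYC target, stem cell marker, hepatocyte secretory, cholangiocyte, stellate cell, endothelial, lipid-associated macrophage, monocyte, T and NK cell, B and plasma cell, glucose, p53, YAP and TGF-β, male-biased and Y-linked genes.

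Camera with preset correlation called 14 of the 37 lists, and 0 of these, the pericentral list included, held with a lowest adjusted p = 0.847 with an estimated correlation. Fry's mixed test, of change in either direction, called 9. Median, mean and test differed in sign for the lipid-associated macrophage, monocyte, acute phase, antigen presentation, bile acid, YAP and TGF-β, immediate early and male-biased lists. The shares of mitochondrial UMIs were higher in both STAM sections (2.10% and 3.67%) than in both DEN+CCl4 sections (1.31% and 1.55%), as were those of ribosomal protein genes.

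Later and earlier sections of a model were set side by side to describe the course of disease, with 1 section at each time and no test. In STAM, Plat, the gene of tissue plasminogen activator, was 74.7-fold higher at 20 than at 16 weeks (log2 ratio 6.22, Poisson interval 5.71 to 6.79), Maoa, a monoamine oxidase, 19.5-fold and Scd1, the stearoyl-CoA desaturase, 11.1-fold. Sdcbp2 (18.5-fold), Cyp2a22 (18.1-fold), Slpi (15.2-fold), Cyp2b9 (11.8-fold), Fabp3 (11.5-fold), Acot3 (10.4-fold) and Tubb2a (9.97-fold) were next. The patch led by Cpe held 70.0% of the Plat, 71.8% of the Maoa and 56.0% of the Sdcbp2 UMIs of STAM20w, and outside it these genes were 27.0-fold, 6.61-fold and 9.79-fold higher than in STAM16w. The patch led by H19 and Afp held 42.8% of the Slpi UMIs, and outside it Slpi was 9.47-fold higher. Slco1a1, an organic anion carrier, was 804-fold lower at 20 weeks (6 UMIs there), Serpina1e 91.8-fold lower, and 8 of the 10 largest drops were major urinary protein genes, from Mup18 (144-fold) and Mup21 (123-fold) through Mup9 (66.9-fold), Mup1 (59.4-fold), Mup7 (46.7-fold), Mup11 (38.2-fold) and Mup17 (37.9-fold) to Mup16 (28.2-fold). Among 2775 genes at 50 CPM or more, 206 were at least 2-fold higher and 103 at least 2-fold lower in the later section. The median log2 ratio of these 2775 genes was 0.19. Ratios were not adjusted for this shift, so these counts and the STAM list medians below include it, as do the random lists.

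In DEN+CCl4, immunoglobulin and acute phase genes stood highest at 30 against 22 weeks. Ighg2b had 3 UMIs at 22 weeks and was 1262-fold higher (log2 ratio 10.30, interval 8.75 to 12.58), Ighg2c and Ighg1 had 0 and were at least 1187-fold and at least 613-fold higher, and Igkc was 38.2-fold higher. The acute phase genes Saa2, Saa1 and Orm2 were 352-fold, 97.9-fold and 78.7-fold higher, Lcn2, the lipocalin of inflamed tissue, 63.3-fold, Mt2, a metallothionein, 24.9-fold and Slpi 13.6-fold. Lower were Mup7 (64.6-fold), Angptl8 (10.7-fold), Mup21 (9.05-fold, or 5.71-fold outside the region of DEN22w led by Etnppl and Pck1), Mup12 (8.18-fold), Mup1 (6.54-fold), Thrsp (6.41-fold), a regulator of lipid synthesis, Mup9 (5.69-fold), Mup17 (5.05-fold), Serpina12 (5.05-fold) and Mup10 (4.93-fold). Among 2906 genes 75 were at least 2-fold higher and 44 at least 2-fold lower, with a median log2 ratio of 0.018. The Mup, Saa and immunoglobulin genes each have near-identical members, so values of single members are uncertain.

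Both models shared part of this. Of 2422 genes compared in both, 20 were higher and 24 lower by 2-fold in both, against 2.877 and 1.301 for independent lists, and 3 moved in opposite directions. The numbers for independent lists treat each gene as a separate draw, while several of the shared lower genes, named below, belong to the Mup family. Pearson's r of the log2 ratios across genes was 0.453 and Spearman's rho 0.330; genes are not independent replicates. The genes highest in both were Slpi, Lcn2, Orm3, Ly6d, Gadd45g, S100a11, Isyna1, Gstm3, Orm2 and Igfbp1, with Ly6d at 3.79-fold in STAM and 5.30-fold in DEN+CCl4 and Gstm3 at 3.05-fold and 2.78-fold. Outside the patch led by Cpe, which held 58.3% of its UMIs in STAM20w, Gstm3 was 1.53-fold higher in STAM. The lowest were Mup7, Mup21, Mup12, Mup1, Mup9, Mup17, Mup10, Mup14, Selenbp2 and Cyp7b1, with Selenbp2 27.1-fold and 4.09-fold lower and Cyp7b1, an oxysterol hydroxylase, 11.7-fold and 3.98-fold lower. Myc was 2.73-fold higher in the later STAM section (log2 ratio 1.45, 1.18 to 1.73) and 2.996-fold in the later DEN+CCl4 section (1.58, 1.08 to 2.11). Mycn had log2 ratios of -0.95 (-2.37 to 0.47) and -0.29 (-1.53 to 0.997), and both intervals held 0.

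By list, male-biased liver genes such as Mup20, Cyp2d9, Selenbp2 and Cyp7b1 had a median log2 ratio of -3.90 in STAM and -1.79 in DEN+CCl4, below all 10000 random lists in both, with 8 of 8 and 7 of 8 members at least 2-fold lower. Members of a list can move together, which random lists of singly drawn genes ignore, so an extreme percentile is not a test result. Female-biased genes such as Cyp2a4, Cyp2b9 and Acot3 had 3.56 in STAM (7 of 7 at least 2-fold higher) and 0.64 in DEN+CCl4 (1 of 3). Lists above at least 99.9% of random lists in both models follow, with medians in the order STAM and DEN+CCl4. Oncofetal and liver tumour genes had 1.62 and 1.40 (Lcn2, Ly6d, Slpi), with 12 of 17 members at least 2-fold higher in each model. Of these genes, Afp went from 12.8 to 54.4 CPM in STAM, or to 22.4 CPM outside the patch led by H19 and Afp. In DEN+CCl4 Afp stood at 5.07 CPM at 22 weeks and 6.59 CPM at 30 weeks. Liver cancer stem cell markers had 1.10 and 1.13, cholangiocyte genes 1.25 and 1.29 (Krt8, Krt18, Spp1). Monocyte and neutrophil genes had 1.31 and 1.66 (Lyz2, S100a8, S100a9), immediate early genes 1.36 and 1.27 (Jun, Junb). The unfolded protein response had 0.82 and 0.98 (Hspa5, Creld2), stellate cell genes 0.65 and 0.84 (Dcn, Col3a1). Kupffer cell genes had 0.74 and 0.72 (C1qb, Cd5l), acute phase genes 0.72 and 1.76 (Hp, Orm1). Some abundant members went against their list: Dusp1 (-0.93) and Ier2 (-0.41) of the immediate early genes, Clec4f (-0.23) of the Kupffer cell genes and Anpep (-0.20) of the stem cell markers were lower in the later DEN+CCl4 section, and Herpud1 (-0.42) of the unfolded protein response in the later STAM section. The shares of mitochondrial and haemoglobin UMIs were also higher in the later section of each model, 3.67% against 2.10% and 1.55% against 1.31%, and 0.0326% against 0.0267% and 0.0199% against 0.00955%. In DEN30w the region led by haemoglobin genes held 71.5% of the Hba-a1, 69.2% of the Hba-a2 and 65.8% of the Hbb-bs UMIs. Mitochondrial UMIs took 3.86% of that region (8.89% of spots) and 1.01 to 1.49% of the other regions of DEN30w. In DEN22w they took 3.74% of the region led by haemoglobin genes (4.73% of spots) and 1.06 to 1.26% of the others. Outside these regions Hba-a1 stood at 19.5 CPM in DEN30w and 16.3 in DEN22w, Hba-a2 at 25.2 and 9.04, and Hbb-bs at 24.3 and 18.5.

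For other lists the medians of STAM and DEN+CCl4 are given in this order; the difference between models was not tested. Lipid-associated macrophage genes had 1.52 and 0.01, with Fabp5 going from 46.8 to 258 CPM in STAM, or to 156 CPM outside the patch led by H19 and Afp. NRF2 and xenobiotic defence genes had 1.21 and 0.35, and lipid droplet genes 1.16 and -0.16, with Plin2 going from 725.5 to 1733 CPM in STAM. YAP and TGF-β targets had 0.87 and 0.42, hypoxia genes 0.77 and 0.10, mitochondrially encoded genes 0.72 and 0.08, and endothelial genes 0.54 and -0.08. Among metabolic lists, cholesterol synthesis genes had 0.71 and -0.18, fatty acid oxidation genes 0.47 and -0.03, lipid synthesis genes 0.36 and -0.32, and bile acid genes -0.32 and -0.14. MYC targets had 0.34 (percentile 95.8) and -0.15 (percentile 0.08). Periportal genes had -0.31 (percentile 0.375) and -0.11 (percentile 15.2), and interferon response genes -0.35 (percentile 0.135) and 0.49 (percentile 99.8). B and plasma cell genes had 3.18 in DEN+CCl4, their summed level going from 27.8 to 588 CPM, and -0.08 in STAM. The remaining lists had 0.33 and 0.58 for antigen presentation, 0.26 and 0.26 for proliferation, 0.06 and 0.45 for p53 and DNA damage, 0.16 and 0.79 for erythroid genes, 0.13 and 0.34 for Wnt targets, 0.10 and -0.18 for hepatocyte secretory genes, 0.05 and 0.07 for pericentral genes, -0.03 and -0.22 for glucose genes, -0.04 and 0.74 for T and NK cell genes, -0.15 and 0.24 for the MYC family, and -0.13 and 0.12 for Y-linked genes. The erythroid median of DEN+CCl4 includes the region of DEN30w led by haemoglobin genes, which held most of the Hba-a1, Hba-a2 and Hbb-bs UMIs.

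**Figure D5:**
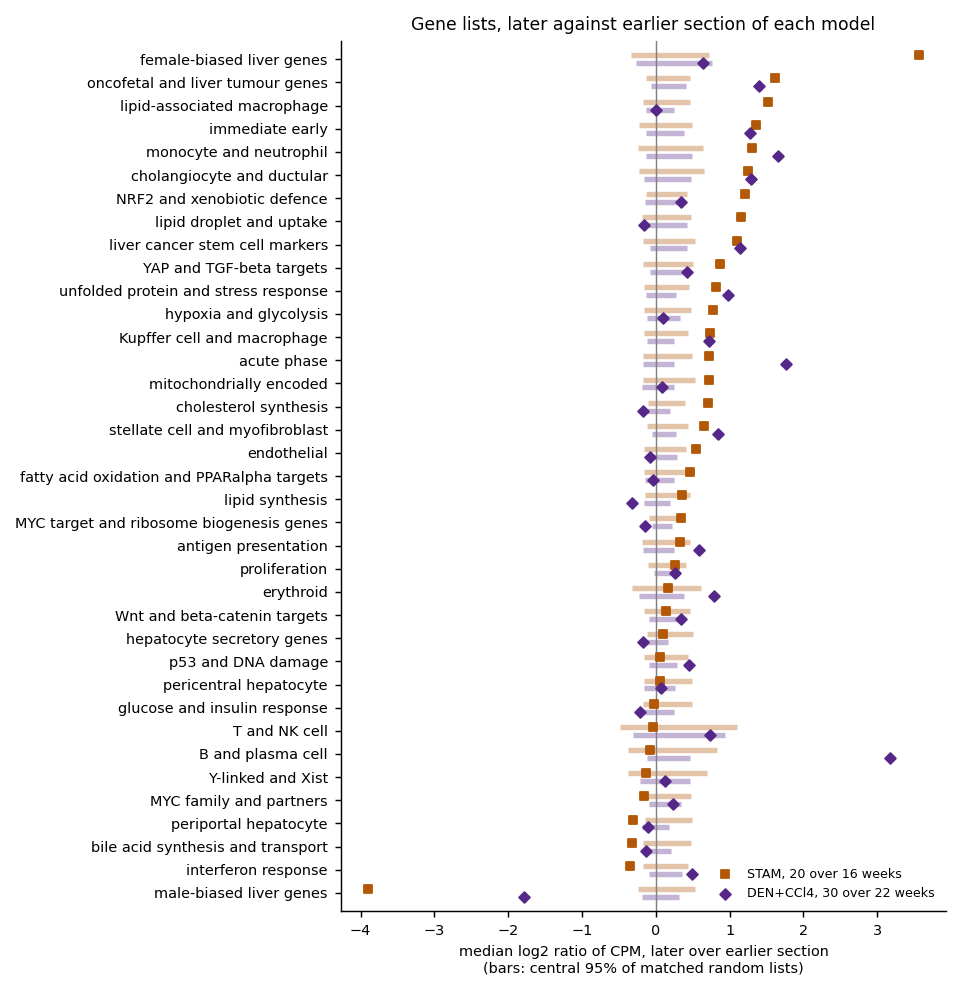
Median log2 ratio, later over earlier section, of the 37 gene lists in STAM and DEN+CCl4 (1 section per time), with bars for the central 95% of 10000 random lists of like expression. Male-biased liver genes lie lowest in both models (-3.90 and -1.79), and B and plasma cell genes lie highest in DEN+CCl4 (3.18).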

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

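The tests of class swaps, of other rarely detected genes, of position within the section and of a lone neighbourhood for Cyp1a2 were chosen after the result was seen, as was the interaction itself; the test of a lone neighbourhood for Nupr1 was not. Set apart as a difference between groups, the change next to Mycn-detected spots was larger in STAM than in DEN+CCl4 by 1.92 on the log2 scale for Nupr1 (SE 0.41, edgeR adjusted p = 0.0121) and by 0.69 for Cyp1a2 (SE 0.14, edgeR adjusted p = 0.00595). As there were 2 sections per model, these p-values do not measure how well the difference repeated across sections.

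The wider pattern, 12 genes called next to Mycn-detected spots, has several technical readings that the tables leave open. Swapping the spot classes within sections gives 8 arrangements, too few for a share under 0.05; the real one gave 12 genes and the highest other 7. Of 50 genes seen in about as many spots as Mycn, 5 gave at least 12 called genes in their own neighbourhood (at most 21), so a count of 12 may arise around any rarely detected gene. With both spot classes taken from the same regions, 2 of the 11 of these genes still tested (Ighm was not) stayed past the threshold, Nupr1 (1.66, SE 0.13, before and 0.75, SE 0.13, after) and Hbb-bs (-0.93, SE 0.14, before and -1.37, SE 0.16, after), while smaller folds ended calls such as those of Meg3 (0.71, SE 0.16, before and 0.25, SE 0.15, after) and Cyp1a2 (0.37, SE 0.07, before and 0.19, SE 0.07, after), so position in the tissue could account for part of the rest, though Hba-a2 (-0.98 before and -0.89 after) and Cyp2a5 (0.29 before and 0.22 after) changed little. In the STAM sections the spots around 1 Mycn-detected spot held 90.1% (STAM16w) and 52.4% (STAM20w) of the neighbour-spot Nupr1 UMIs. This is a candidate explanation of the Nupr1 difference between models too, though no fit without these spots was made. For Cyp1a2 the shares of 17.9% in STAM16w and 74.8% in STAM20w lie on both sides and leave a lone neighbourhood undecided. In STAM20w the leading spot was the same for both genes, the 1 Mycn-detected spot of the patch led by Cpe. Cyp1a2 stood at 1347 CPM in that patch against 135 in the other spots. A biological difference between models stays open and untested.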

How the results depend on the processing

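Settings of at least 5000 UMIs per spot, of regions without haemoglobin or mitochondrial leading genes, and every alternative of the Mycn-detected spot fit and of the interaction were chosen after seeing the data. No paired analysis was possible because the groups share only replicate number 1, with 1 section each. Where leaving out a section leaves 1 in a model, that lone section is assumed to vary like the other groups. The planned fit of Mycn-detected spots and its interaction gave no value (under 20 pairs per section), nor did spots with at least 2 Mycn UMIs (0 spots) or the grouping of Mycn in DEN22w thinned to 2000 UMIs (0 spots).

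Next to Mycn-detected spots 12 genes were called; DESeq2 gave 0 (32 at an unadjusted p under 0.05), no section block 0 (29) and matching within regions 3, with Ighm not tested. Leaving out a section gave 1 to 20, with 20 without STAM16w, 10 of the 12 among them, and 1 without STAM20w, 0 of the 12. All 12 kept their sign in each setting that tested them. Of the values of named genes 70 kept their call and 59 lost it. In the Mycn-detected spot fit, 0 calls became 1 without the filter on low counts, 2 without depth matching and 0 to 1 on leaving out a section (1 without STAM16w and 1 without DEN22w). Signs turned there for Oat (-0.081 without depth matching, -0.20 matched within regions), Igfbp1 (-0.26 and -0.24) and Ifi27 (-0.043 without depth matching). The 2 interaction genes became 0 with DESeq2 and 0 without the filter on low counts, both genes keeping their sign.

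Between models 63 calls became 1517 with DESeq2, 1872 without the filter on low counts and 2 to 922 on leaving out a section: 922 without STAM16w, which held all 63, 71 without STAM20w, which held 36 of them, 5 without DEN22w and 2 without DEN30w, the last pair with fewer DEN+CCl4 sections. The 63 kept their signs throughout. Mycn (-0.15) ranged from -0.74 to 0.35 on leaving out a section, turning sign without STAM20w (0.35) and without DEN22w (0.077). Of the values of named genes 257 stayed, 56 lost and 2 gained their call. Camera with preset correlation called 14 lists next to Mycn-detected spots, 5 in Mycn-detected spots and 14 between models, against 0, 0 and 1 by fry; with an estimated correlation it called 0 between models. At 20 CPM, genes 2-fold apart between times were 527 in STAM (309 at 50 CPM), 184 in DEN+CCl4 (119) and 72 in both (44), as more genes were compared; of the values of named genes 310 stayed and 30 moved. Unthinned, Mycn-detected shares were 0.481%, 0.353%, 0.401% and 0.472%, since detection grows with depth. Regions numbered 7 in DEN22w at resolution 1 and 3 in DEN30w at resolution 0.3. Where a call ended for another reason than fewer sections, the cause was not tested.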

Other observations

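The tests of the animals' sex, of Mup paralogs and of single regions, and the test over all pairs of sections, were chosen after the results were seen; those of strain and of other ways to pair the sections were not. The patches of STAM20w differed in the fixed gene lists, given here as log2 fold of the summed CPM over the other spots of the section, from 1 section and without a test. The patch led by Cpe, Slc7a11 and Gpx2 had Wnt and β-catenin targets at 2.23 (2910 against 619 CPM), NRF2 and xenobiotic defence genes at 1.65, pericentral genes at 1.64 and periportal genes at -1.73. The patch led by H19 and Afp had stem cell markers at 1.81 and lipid droplet genes at 1.10, with Wnt targets at -2.31 and male-biased liver genes at -1.80. The region led by Ankrd1 and Dcdc2a had YAP and TGF-β targets at 1.90 and cholangiocyte genes at 1.54. Some list genes, such as Nkd1, Gpx2, Cd24a, Ankrd1 and Krt7, are also leading genes of these regions and so helped to define them.

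In STAM16w the 19-spot patch led by Mtmr11 and Nupr1 had Wnt targets at 2.31, a list that holds Nkd1, itself a leading gene of the patch. In DEN22w the region led by Gpnmb and Mmp12 had monocyte genes at 1.39 and Wnt targets at 1.26. In DEN30w the region led by Meg3 and Cd74 had female-biased genes at 1.22, T and NK cell genes at 1.12 and B and plasma cell genes at 1.03.

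Male-biased liver genes were lower in the later section of both models. A female animal in the later section is argued against by Xist at 1 UMI or fewer in every section and by the summed Y-linked genes, whose log2 ratio was -0.15 in the model where it lay farthest from 0. Reads shared between Mup paralogs do not account for it, since the male-biased genes outside the Mup family had medians of -1.99 or lower in both models. A loss limited to some regions is argued against by the genes outside the Mup family, whose median level in any region of at least 100 spots in the later section was at most 31.5% of the earlier section's in DEN+CCl4 and 7.89% in STAM (their summed level at most 66.5% and 22.4%); the sum of the whole list, mostly Mup20, was at most 47.6% and 8.88%. Disease, age and a difference between animals stay open and were not tested, with 1 section per time.

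Some genes were far lower in one model than in the other, such as C1rb, Hamp2, Cyp26a1 and Fitm1. Between both models, 18 genes were at 5 CPM or more in both sections of one and at least 20-fold lower in both of the other. The other ways to pair the 4 sections gave 4 and 0, which argues against a pattern found under any pairing. With so few pairings possible, these counts cannot exclude chance. Single pairs of sections of the same model held up to 36 such genes, as many as the pair of different models with the fewest (36 to 104), so part of the pattern may be a difference found between any pair of sections. Whether the animals of the models differed in strain could not be told apart from the model: H2-Ea, the marker chosen for it, matched 0 genes of the files.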
